A study of Homo sapiens with 15 samples.

How the data were processed

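RNA was measured by sequencing in 15 libraries of cultured human primary T cells, 3 triplicate wells in each of 5 groups: activated at day 2, acute and chronic at day 4, and acute and chronic at day 8. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a TruSeq kit that does not keep strand, sequenced as paired ends on a NextSeq instrument. The deposited file holds raw counts per gene as whole numbers in the column layout of featureCounts, per the file header. The submitters' processing notes name FastQC 0.12.0, Trim Galore 0.6.10, STAR 2.7.0a, SAMtools 1.19.2, featureCounts 2.0.6 and DESeq2 1.42.0, and the genome builds mm10 and hg38, without saying what each was used for. The coordinates in the file are those of hg38 (GRCh38), including alternate contigs. The annotation release, the treatment of reads with several matches and the strand setting are not given in the sources used here.

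The table holds 62130 gene entries for all 15 libraries. Of these, 518 that lie only on the Y chromosome, with XIST and TSIX, were left out, since they carry a donor's sex, and 61612 were used. Another 2321 entries are listed both on a chromosome and on another contig; they were kept, their levels are uncertain, and leaving them out was an alternative chosen after seeing the data. Coordinates printed are those given in the file, on GRCh38, and were checked against GENCODE v29. Of 36626 symbols found there, 36608 overlapped the position given in the file. Genes that share sequence with a close copy are uncertain where reads could be split, among them XCL1 and XCL2, GZMB and GZMH, the KLRC genes, TRGC1 and TRGC2, the IFIT genes and the histones, and without strand a gene and its antisense partner cannot be separated.

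Counts were analysed in R 4.3.3 with edgeR 4.0.16. TMM factors scaled the libraries, filterByExpr with the 5 groups kept 22703 genes, and all 15 libraries entered 1 quasi-likelihood fit with a coefficient per group and no covariate. The 7 comparisons were chronic against acute at day 4 and at day 8, the difference between these effects, acute day 4 against day 2, acute day 8 against day 4, and the same steps in chronic cells. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and the number with an absolute log2 fold change of at least 1 was counted too. CPM are edgeR's with TMM factors. The depth of each library, at least 81155499 counts, makes counting error small beside the spread between wells, except for genes with few counts; 95% counting intervals and the floor of 3 counts per group cover counting error only.

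Before the data were examined, 34 gene lists with 643 genes were fixed, of which 642 were in the table and 603 tested. They held inhibitory receptors, exhaustion-associated transcription factors, naive and memory genes, cytotoxic effectors, cytokines and chemokines, costimulatory molecules, immediate early genes, negative regulators of receptor signalling, and ubiquitin ligases with deubiquitinases. Others held proteasome subunits, chaperones, and genes of the unfolded protein response, ATF4 and amino acid response, glycolysis, hypoxia, respiratory chain, cholesterol synthesis, DNA replication, mitosis, p53 and interferon response. The rest were tissue residency genes, natural killer receptors, CD8 identity genes, markers of CD4, gamma delta, B, monocytic, dendritic, erythroid with platelet, and fibroblast with epithelial cells, and ribosomal proteins, histones and mitochondrial transcripts. A list with at least 5 tested genes was tested with camera of limma 3.58.1 against all other genes, with a preset correlation of 0.01 and adjustment over the lists of a comparison. The alternatives were an estimated correlation and fry, which asks whether the genes of a list move on balance one way, without comparing them with other genes.

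The genes named were set by a rule fixed at the same time. It took 19 core genes whatever their result, the 6 largest increases and 6 largest decreases in each chronic against acute comparison, 5 each way in the difference between days and 3 each way in each comparison over time. These had to pass the threshold, reach a mean of 10 CPM in the higher group (in at least 1 of 4 groups for the difference) and, except for the difference, have no overlap between the libraries compared. Up to 3 examples per list needed 5 CPM, and markers of other cells 1 CPM in any group. Genotype-dependent families such as HLA, receptor segments, non-coding and clone names and antisense genes were not eligible. Some genes that the rule took are not reported here.

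The alternatives fixed beforehand were DESeq2 1.42.0 size factors (RLE) or upper quartile factors in place of TMM, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate number as a block, a fit of only the libraries compared, the DESeq2 test, limma-voom, and leaving out each library in turn. No pair of wells agreed within sampling noise, since the chi-square per degree of freedom between replicates, over genes with at least 20 counts, lay between 3.18 and 46.3. The fit was tested on counts simulated for 22703 genes with 200 of them changed, and 21887 genes passed the filter. It made 9 false calls in the day-4 comparison, 3 in the day-8 comparison and none in the difference between days. The 9 stood beside 31, 48 and 61 recovered genes that had been changed 1.5-fold, 2-fold and 4-fold. Changed genes moved by the same fold at both days, so that no true difference between days was there to find. The counts were drawn with the model and spread of the fit, so that a misfit of the model could not show. Changed genes that the filter removed counted as not recovered. Far fewer genes changed there than were called in the real data.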

Results

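The data were RNA-sequencing read counts from cultured human primary T cells, labelled as CD8 T cells, in 15 libraries of 5 groups with 3 triplicate wells each. Cells were stimulated through the T cell receptor with plate-bound anti-CD3 together with anti-CD28 until day 2, and were then grown in IL-7 and IL-15. One arm received no further receptor stimulation (acute) and the other was kept on plate-bound anti-CD3 (chronic). RNA was taken at day 2 from activated cells and at days 4 and 8 from both arms. The total count per library was 89247829 to 112822714 at day 2. It was 82840995 to 106933317 in acute and 81155499 to 90315634 in chronic cells at day 4, and 85161486 to 90930991 and 86704996 to 97460165 at day 8. The number of donors behind the wells is not given in the sources used here, so that the p-values measure the spread between wells, which may be technical. Levels below are CPM (counts scaled by library size) as mean ± SD of 3 libraries, log2 fold changes carry their standard error after ±, and adjusted p-values come from edgeR's quasi-likelihood test for genes and from camera for gene lists.

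Replicate wells lay close together relative to the differences between groups. The Pearson correlation of log2 CPM between wells of a group lay between 0.9925 and 0.9952, and the biological coefficient of variation was 7.5%. The first principal component held 48% of the variance and ordered the groups from acute day 8 through acute day 4 and activated day 2 to chronic day 4 and chronic day 8. The second held 24.5% and set day 2 apart from all later libraries.

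**Figure D1:**
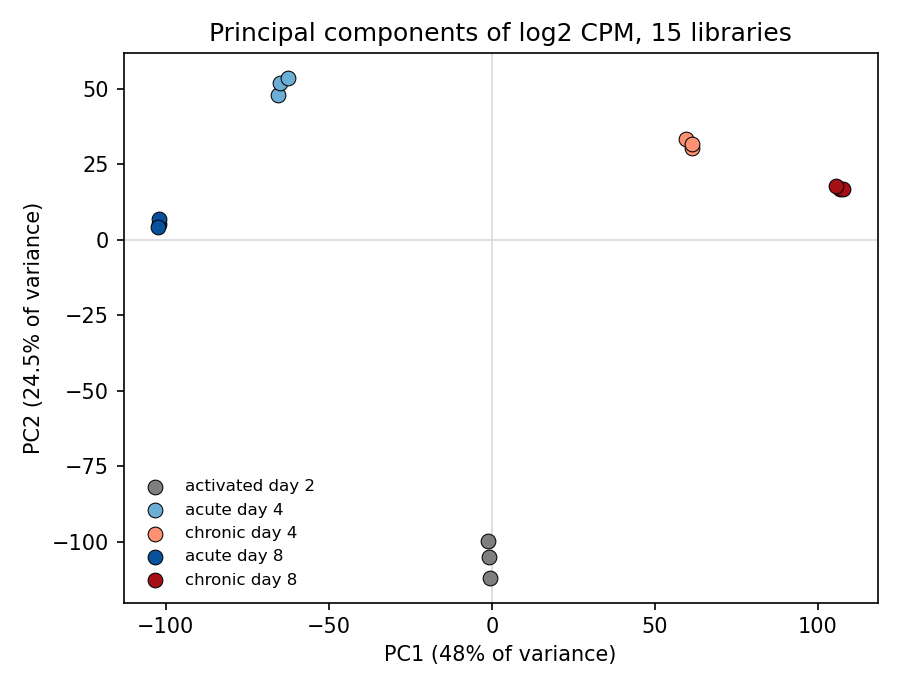
Scores of the 15 libraries on the first and second principal components of log2 CPM, with 1 point per library coloured by group. Along PC1, which held 48% of the variance, the day-2 libraries lay near 0, the acute libraries at negative scores and the chronic libraries at positive scores, with day 8 farther out than day 4.

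The day-4 comparison asked what 2 further days of receptor stimulation did to cells that had all been activated alike. Chronic cells held 36.5 times as much mRNA for the cytotoxic protease granzyme B (GZMB, chromosome 14, 24630954 to 24634267 of GRCh38), with 6550 ± 290 against 180 ± 16 CPM (log2 5.19 ± 0.08). The nuclear receptor gene NR4A3 (chromosome 9, 99821855 to 99866891), which is induced by T cell receptor signalling, stood at 261 ± 6.4 against 2.77 ± 0.13 CPM, and the costimulatory receptor TNFRSF9 (4-1BB) at 429 ± 12 against 11.6 ± 0.43. KLF2, a transcription factor of quiescent and circulating T cells (chromosome 19, 16324826 to 16328685), was 23.9-fold lower, at 3.41 ± 0.37 against 81.7 ± 7.6 CPM. Of 22703 genes tested, 6008 were higher and 6584 lower in chronic cells, 2321 and 1865 of them by at least 2-fold. The filter of 1 CPM, which tests fewer genes, lowered the 2-fold counts to 1372 and 956. With RLE scaling 6416 were higher and 6031 lower, and with the DESeq2 test 6190 and 5526.

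The largest increases at day 4 were in SERPINA1, the gene of alpha-1 antitrypsin (log2 8.95), the G protein subunit gene GNG4 (7.82), and the B cell attracting chemokine gene CXCL13 (6.68). NR4A3 (6.55), the extracellular matrix gene FMOD (6.23) and the transcription factor gene ZBED2 (6.14, 31.9 ± 3.9 in acute and 2250 ± 78 CPM in chronic cells) followed. SERPINA1 is also annotated on an alternate contig, which leaves its level uncertain. The largest decreases were in RAP1GAP2 (-5.39), the calcium channel gene CACNA1I (-4.85), VSIG1 (-4.58), KLF2 (-4.58), the chemokine receptor gene CCR2 (-3.66) and the aquaporin gene AQP3 (-3.52). Among the genes named whatever their result, the inhibitory receptors LAG3 (524 ± 24 against 58.8 ± 6 CPM, log2 3.16 ± 0.09), CTLA4 (422 ± 23 against 111 ± 8.2, 1.93 ± 0.06) and HAVCR2 (291 ± 11 against 141 ± 1.9, 1.04 ± 0.05) rose, as did ENTPD1 (0.32). TIGIT stood at 87.2 ± 1.6 against 90.3 ± 1.3 CPM (adjusted p = 0.33). PRF1, which encodes perforin (1.82), IFNG (3.35, from 8.06 ± 0.48 to 82.2 ± 5.9 CPM), IL2 (3.18), the chemokine receptor CCR7 (0.60) and the ubiquitin ligase adaptor KLHL6 (0.46 ± 0.05) also rose. IL2 lay at only 0.718 ± 0.22 against 0.0743 ± 0.057 CPM, and its log2 value was 4.05 without acute day-4 replicate 3. The interleukin-7 receptor gene IL7R (-1.93, 202 ± 3.6 against 768 ± 30 CPM), LEF1 (-0.29) and the proliferation marker MKI67 (-0.59) fell. TOX, a transcription factor of T cell exhaustion, was low in both arms (4.09 ± 0.21 against 5.13 ± 0.65 CPM, log2 -0.32, adjusted p = 0.012). This call was lost without acute day-4 replicate 1 (adjusted p = 0.099) or chronic day-4 replicate 1 (adjusted p = 0.054). TCF7, a factor of memory-like cells, gave -0.14 (adjusted p = 0.087), which passed without acute day-4 replicate 3 (adjusted p = 0.047), with upper quartile scaling (adjusted p = 0.022) and with the filter of 1 CPM (adjusted p = 0.033).

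Among the lists of T cell activation and effector genes at day 4, 17 of 20 exhaustion-associated transcription factors rose and 2 fell (adjusted p = 8.3e-45), including NR4A1 at 221 ± 27 against 3.44 ± 1 CPM and EGR3 at 428 ± 12 against 6.5 ± 0.34. Of 21 cytokines and chemokines, 19 rose and none fell, or 1 when adjusted over the list alone (adjusted p = 2.1e-38), with IL3 73.8-fold and XCL1, which shares nearly all its sequence with XCL2, 51.2-fold higher. Of 18 immediate early and AP-1 genes, 17 rose (adjusted p = 9e-25), with EGR1 27.7-fold, FOS 26.4-fold and DUSP2 16.5-fold higher. Of 15 costimulatory receptors and ligands, 14 rose and 1 fell (adjusted p = 1.2e-15), with TNFRSF18 at log2 3.34. Of 19 cytotoxic effector genes, 13 rose and 5 fell (adjusted p = 8.5e-13), with FASLG 6.65-fold and GZMH 4.13-fold higher. The 28 negative regulators of receptor signalling split 18 up and 7 down (19 and 7 adjusted over the list alone; adjusted p = 1.6e-12), led by RGS16 (39.5-fold) and DUSP4 (8.89-fold). The 28 ubiquitin ligases and deubiquitinases split 20 up and 3 down (adjusted p = 1.1e-09, but adjusted p = 0.062 with an estimated correlation), with NDFIP2 5.24-fold, BIRC3 5.21-fold and the NF-kappaB inhibitor TNFAIP3 3.3-fold higher. The 16 inhibitory receptors split 8 up and 6 down (adjusted p = 0.013, but adjusted p = 0.21 with an estimated correlation), from CD200 (15.4-fold higher) to CD101 (5.89-fold lower). For the calls above without a value for the estimated correlation, camera with that setting gave far larger adjusted p-values, all below 0.05. They were 2.2e-06 for exhaustion-associated factors, 0.00021 for cytokines, 0.0087 for immediate early genes, 9.7e-05 for costimulatory molecules, 0.0082 for cytotoxic effectors and 9.7e-05 for negative regulators. In the other lists fixed beforehand, counts adjusted over the list alone equalled those over all genes unless given.

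At day 4 all 22 ATF4 and amino acid response genes tested rose (adjusted p = 1.7e-27), such as STC2 (13.4-fold), the folate enzyme gene ALDH1L2 (7.3-fold) and the amino acid transporter SLC7A5 (4.71-fold). Of 22 cholesterol biosynthesis genes 17 rose and 3 fell (adjusted p = 1.5e-11), with SQLE 7.68-fold and HMGCS1 4.38-fold higher. Of 22 p53 target genes 11 rose and 4 fell (adjusted p = 0.0012), led by GADD45A (6.21-fold) and PMAIP1 (4.38-fold). The remaining calls among the stress, metabolic and cell cycle lists were lost with an estimated correlation, though they passed with fry, which compares with no other genes. Glycolysis genes rose in 16 of 20 (adjusted p = 2.9e-05, but adjusted p = 0.31 with an estimated correlation), with PKM 2.63-fold and PGAM1 2.48-fold higher. Interferon-stimulated genes rose in 18 and fell in 7 of 28 (adjusted p = 0.00037 and adjusted p = 0.43 with an estimated correlation), with IFIT3 4.64-fold higher. Chaperone genes rose in 19 and fell in 2 of 22 (adjusted p = 0.0025 and adjusted p = 0.5 with an estimated correlation), with HSP90AB1 2.73-fold higher. Unfolded protein response genes rose in 14 and fell in 2 of 20 (adjusted p = 0.0053 and adjusted p = 0.21 with an estimated correlation), with HSPA5 2.38-fold higher. Hypoxia-inducible genes rose in 9 and fell in 3 of 18 (adjusted p = 0.018 and adjusted p = 0.49 with an estimated correlation), with BHLHE40 5.17-fold higher. All 25 mitosis genes fell, such as KIF11 (1.84-fold) and CENPF (1.81-fold; adjusted p = 1.5e-06, but adjusted p = 0.14 with an estimated correlation). Of 25 DNA replication genes 17 fell and 3 rose (18 and 3 adjusted over the list alone; adjusted p = 0.00097 and adjusted p = 0.2 with an estimated correlation), with CCNE2 1.81-fold lower. Proteasome subunits rose in 16 and fell in 1 of 29, with PSMD13 1.68-fold higher. The list test gave adjusted p = 0.053, which became 0.036, 0.033 and 0.038 without acute day-4 replicate 1, acute day-4 replicate 3 and chronic day-4 replicate 1, and 0.037 with RLE scaling.

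The other lists did not pass as sets at day 4 or, for gamma delta T cells, dendritic cells and erythrocytes with platelets, held too few genes for a test, and markers of other cells moved as follows. Naive and memory genes split 8 up and 8 down of 19 (median log2 -0.06), with BACH2 3.31-fold higher. Respiratory chain genes split 8 and 7 of 34 (median 0.01, but 9 against 3 with RLE scaling, and -0.04 and 7 against 9 with upper quartile scaling), with NDUFV2 2.85-fold higher and ATP5PB 1.4-fold lower. Tissue residency genes split 6 and 5 of 14, with CRTAM 4.94-fold higher and CXCR3 4.03-fold lower; their median was -0.01, their mean -0.19 and the direction of the test upward, and the median changed sign with other scaling. Natural killer receptors split 5 and 7 of 16, with KLRC1 8.65-fold higher and CD300A 5.09-fold lower (median -0.15, mean 0.14, direction of the test upward). CD8 T cell identity genes split 2 and 4 of 11, with CD2 1.98-fold higher and CD8B at 49.9 ± 1.2 against 96.3 ± 4 CPM (log2 -0.95); CD8A, chosen after its values were seen, gave -0.49. Of the CD4 and helper markers 4 of 7 rose and 2 fell, with CD4 itself at 347 ± 10 against 331 ± 20 CPM (adjusted p = 0.26). Of the gamma delta T cell markers 1 rose and 3 fell, with TRDC at 5.65 ± 0.34 against 8.05 ± 0.32 CPM and TRGC2 at 10.8 ± 0.47 against 17 ± 0.49. Of 9 B cell markers 1 rose and 5 fell (2 and 5 adjusted over the list alone), with MS4A1 (CD20) at 27.6 ± 0.77 against 46.5 ± 0.71 CPM. Among monocyte markers 2 rose and 1 fell of 7 (median 0.04, below 0 with upper quartile scaling). Among dendritic cell markers 1 rose and 2 fell of 3, with LAMP3 at 40.6 ± 3 against 12.7 ± 0.78 CPM. Among erythrocyte and platelet markers 1 rose and 1 fell of 3, and among fibroblast and epithelial markers 3 of 5 rose, with COL1A1 at 2.37 ± 0.22 against 0.196 ± 0.1 CPM. Ribosomal protein genes rose in 9 of 36 (6 adjusted over the list alone), histone genes in 3 of 14 (2 adjusted over the list alone), and mitochondrial transcripts in 6 of 15 with 1 lower. Mitochondrial transcripts took 7.6% ± 0.2 of counts in chronic and 7.46% ± 0.1 in acute cells. In data simulated for this comparison with 200 genes changed, 46.3% of those changed 1.5-fold, 71.6% of those changed 2-fold and 92.4% of those changed 4-fold were recovered. In the real comparison 55.5% of genes were called, which makes the adjustment less strict, so these shares do not carry over to it.

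**Figure D2:**
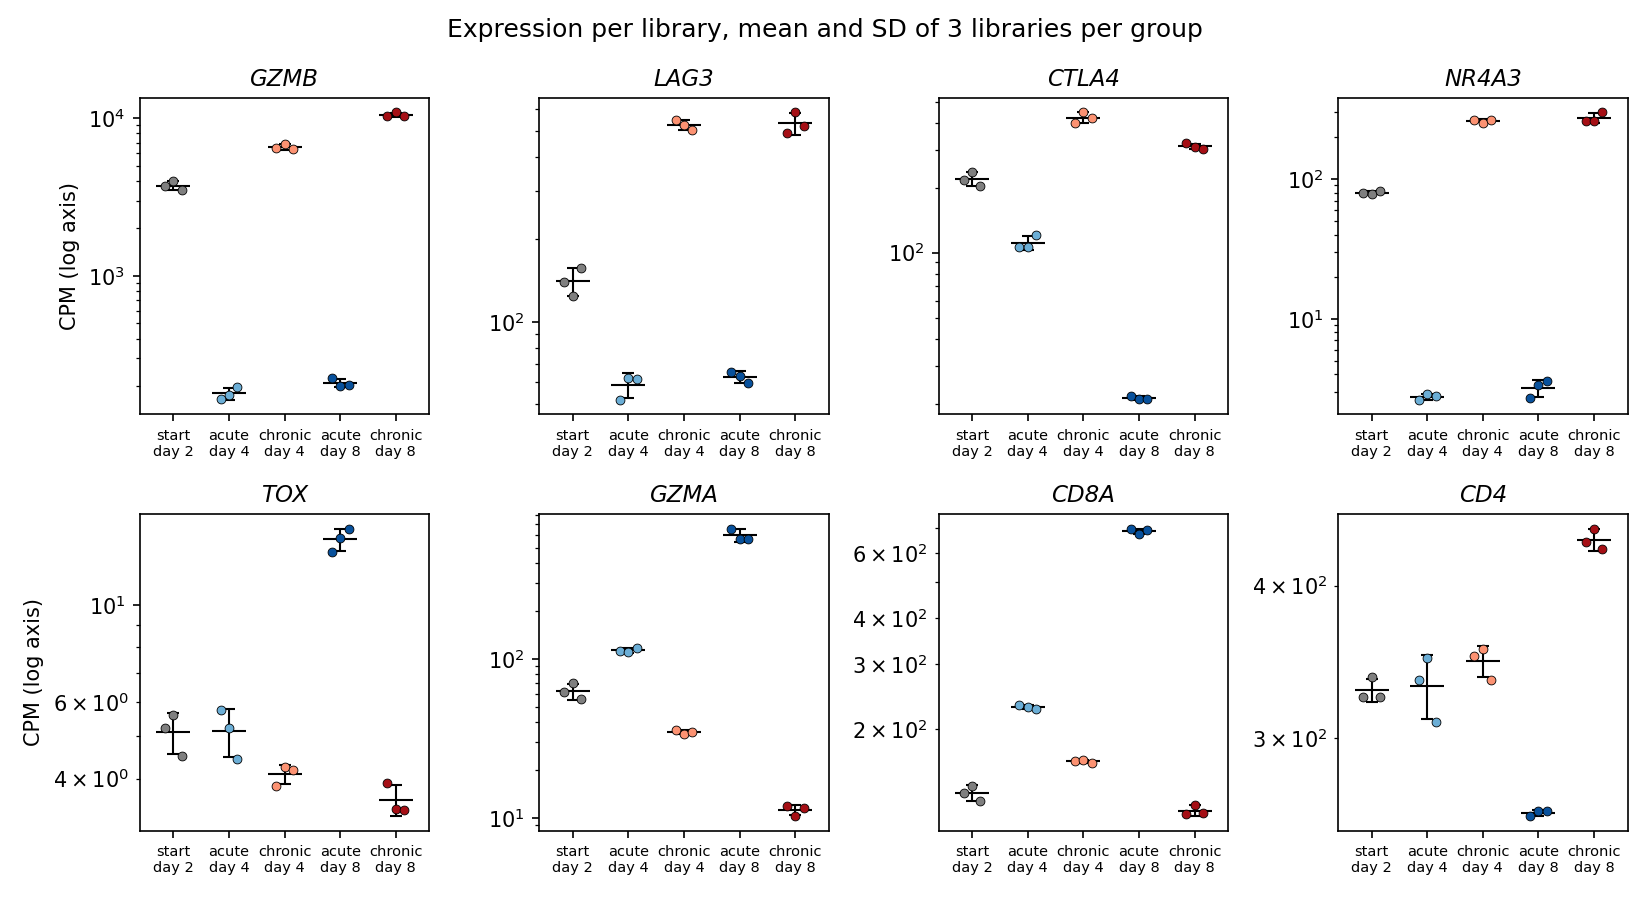
CPM (log axis) of GZMB, LAG3, CTLA4, NR4A3, TOX, GZMA, CD8A and CD4 in each of the 15 libraries; points are libraries, the wide bar the mean and the whiskers the SD of 3 libraries, with the activated cells marked as start. GZMB reached 6550 and 10500 CPM in chronic cells at days 4 and 8 against 180 and 209 in acute cells, while CD8A was highest, at 688 CPM, in acute cells at day 8.

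The day-8 comparison asked how the arms differed after 6 days with or without receptor stimulation. GZMB stood at 10500 ± 340 against 209 ± 13 CPM (log2 5.65 ± 0.09). The related protease granzyme A (GZMA, chromosome 5, 55102646 to 55110252) went the other way, with 11.2 ± 0.84 against 596 ± 54 CPM (-5.73 ± 0.09). The type VI collagen gene COL6A3 (chromosome 2, 237324003 to 237414328) reached 824 ± 41 CPM from 1.36 ± 0.11 in acute cells, and CXCL13 reached 135 ± 6.5 from 0.0837 ± 0.026. Transcripts of the CD8 co-receptor were lower in chronic cells, with CD8A (chromosome 2, 86784610 to 86808396) at 121 ± 4 against 688 ± 11 CPM (-2.51 ± 0.05) and CD8B at 39.2 ± 1.9 against 218 ± 6.8 (-2.47 ± 0.05). CD4 (chromosome 12, 6786858 to 6820799) was higher, at 436 ± 8.7 against 261 ± 1.5 (0.74 ± 0.05). In all, 7486 genes were higher and 7558 lower, 3877 and 2898 of them by at least 2-fold (2147 and 1671 with the filter of 1 CPM). The direction with more genes turned with several settings, for example to 7817 higher and 7156 lower with upper quartile scaling.

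The largest increases at day 8 besides CXCL13 and COL6A3 were in FMOD, the homeobox gene BARX2, the neuroendocrine transcription factor gene INSM1 and SERPINA1. Their counts in acute cells were so few that only ratios of counts are given. These were 3100 (95% counting interval 859 to 25600) for FMOD, 1730 (478 to 14300) for BARX2 and 899 (307 to 4360) for INSM1. SERPINA1 had no counts in acute cells and was at least 1710-fold higher. Without acute day-8 replicate 1, which held all counts of BARX2 and INSM1 in acute cells, the fitted log2 values of BARX2 and INSM1 went from 10.52 and 9.65 to 13.26 and 12.9. The largest decreases were in the prostaglandin D2 receptor gene PTGDR2 (-8.38, from 56.4 ± 0.46 to 0.171 ± 0.098 CPM), VSIG1 (-7.93), PLXNA4 (-7.78), RAP1GAP2 (-7.67), CCR2 (-7.23) and KLF2 (-7.2). Of the genes named whatever their result, LAG3 (531 ± 47 against 62.9 ± 3.1 CPM), CTLA4 (311 ± 9 against 21.2 ± 0.41), HAVCR2 (283 ± 9.9 against 123 ± 3.5) and ENTPD1 (27.6 ± 1.3 against 8.92 ± 0.22) were higher, with log2 values of 3.08, 3.87, 1.2 and 1.63. TIGIT (-0.96 ± 0.04) and TOX (3.57 ± 0.29 against 14.1 ± 0.83 CPM, -1.99 ± 0.1) were lower. IFNG (2.42), IL2 (4.52), CCR7 (1.24), KLHL6 (0.97 ± 0.05) and TCF7 (0.28) were higher, and IL7R (-1.6) and MKI67 (-0.44) lower. PRF1 gave 0.06 (adjusted p = 0.46) and -0.02 without chronic day-8 replicate 2. LEF1 gave -0.11 (adjusted p = 0.047). This call was lost with most alternatives, among them the RLE scaling (adjusted p = 0.16), no filter on low counts (adjusted p = 0.25, the highest) and the replicate block (adjusted p = 0.075), and in most fits that left out 1 library, where the adjusted p rose to at most 0.14.

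At day 8, 19 of 21 cytokines and chemokines were higher and 2 lower (adjusted p = 9.8e-25), with IL21 65.3-fold and IL3 270-fold higher. Of 20 exhaustion-associated transcription factors 14 were higher and 6 lower (adjusted p = 2.1e-15), with EGR3 104-fold, NR4A1 101-fold and NR4A3 85-fold higher and with EOMES, chosen after its values were seen, at 8.48 against 62.1 CPM. Costimulatory molecules were higher in 12 and lower in 3 of 15 (adjusted p = 0.0061, but adjusted p = 0.11 with an estimated correlation), with TNFRSF9 14.1-fold higher. Immediate early genes were higher in 12 and lower in 6 of 18 (adjusted p = 4.7e-05 and adjusted p = 0.33 with an estimated correlation), with BATF3 7.86-fold higher. Ubiquitin ligases and deubiquitinases were higher in 16 and lower in 8 of 28 (adjusted p = 0.00033 and adjusted p = 0.31 with an estimated correlation), with NDFIP2 9.33-fold, USP18 5.78-fold and SIAH2 4.17-fold higher. Tissue residency genes were lower in 10 and higher in 3 of 14 (adjusted p = 0.0013, but adjusted p = 0.077 with an estimated correlation), with the residency factor ZNF683 145-fold and ITGA1 9.79-fold lower. Natural killer receptors were lower in 11 and higher in 5 of 16 (adjusted p = 0.029 and adjusted p = 0.39 with an estimated correlation; 0.061 once genes on alternate contigs were left out, which was tried after seeing the data), with KLRB1 26.2-fold and FCGR3A 10-fold lower. CD8 T cell identity genes were lower in 9 and higher in 1 of 11 (adjusted p = 0.0011 and adjusted p = 0.19 with an estimated correlation), with LCK, a kinase of T cell receptor signalling, 1.99-fold lower. The 19 cytotoxic effector genes split 9 and 8 (median log2 0.06, mean -0.39, direction of the test upward), and KLRG1 was 28.1-fold lower. The 16 inhibitory receptors split 6 and 7, with CD200 71.4-fold higher and CD244 36.9-fold lower. Their median was -0.02, which changed sign with other scaling, and their mean 0.27. The list test pointed upward and gave adjusted p = 0.14, or 0.014 without genes on alternate contigs such as LAIR1. The 28 negative regulators split 11 and 13 (median -0.12, mean 0.25, direction of the test upward), with RGS16 42.8-fold and DUSP4 12.3-fold higher and the cytokine-induced CISH 4.36-fold lower. The 19 naive and memory genes split 9 and 10, with MYB 10.7-fold higher and KLF3 23.9-fold lower.

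Of the stress and metabolic lists at day 8, 21 of 22 ATF4 and amino acid response genes were higher and none lower (adjusted p = 1.4e-30), with ALDH1L2 45.4-fold and CHAC1 22.3-fold higher. STC2 stood at 20.8 ± 1.4 against 0.0374 ± 0.035 CPM (log2 9.04, or 10.1 without acute day-8 replicate 2). Cholesterol biosynthesis genes were higher in 15 and lower in 3 of 22 (adjusted p = 1.3e-05), with SQLE 9.93-fold and STARD4 4.55-fold higher. Interferon-stimulated genes were higher in 23 and lower in 4 of 28 (adjusted p = 3.9e-06, but adjusted p = 0.35 with an estimated correlation), with IFI44L at 557 ± 58 against 30 ± 1.2 CPM and MX1 at 292 ± 45 against 46.1 ± 1. Glycolysis genes were higher in 16 and lower in 1 of 20 (adjusted p = 0.012 and adjusted p = 0.61 with an estimated correlation), with PFKFB4 3.59-fold higher. Hypoxia-inducible genes were higher in 10 and lower in 3 of 18 (adjusted p = 0.027 and adjusted p = 0.6 with an estimated correlation), with VEGFA 13-fold and P4HA2 8.19-fold higher. The remaining lists did not pass as sets. Chaperone genes split 12 higher and 3 lower of 22, with HSPB1 3.98-fold higher and DNAJB1 2.47-fold lower, and unfolded protein response genes 3 and 12 of 20, with CRELD2 2.95-fold lower and EDEM1 2.83-fold higher. DNA replication genes split 12 and 10 of 25, with MCM6 2-fold higher and CCNE2 2.2-fold lower, and mitosis genes 12 and 5 of 25, with BUB1B 1.55-fold higher and KIF11 1.46-fold lower. The p53 target genes split 6 and 13 of 22 (adjusted p = 0.087, and 0.049 without acute day-8 replicate 3), with PHLDA3 7.41-fold and SESN1 4.8-fold lower. Proteasome subunits split 7 and 6 of 29, with PSMC5 1.58-fold lower, and respiratory chain genes 8 and 7 of 34 (7 and 6 adjusted over the list alone); both medians were 0.01 while their tests pointed downward.

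Markers of other cells at day 8 moved beside these lists. All 4 gamma delta T cell markers were lower in chronic cells, with TRDC at 3.82 ± 0.48 against 15.6 ± 0.82 CPM and TRGC2 at 7.45 ± 0.76 against 34.7 ± 0.84. Of the CD4 and helper markers 4 of 7 were higher, with CD40LG 1.53-fold, and 3 lower, with FOXP3 at 2.6 ± 0.28 against 6.9 ± 0.71 CPM. The ratio of CD8A to CD4 CPM was 0.276 ± 0.0051 in chronic and 2.64 ± 0.056 in acute cells at day 8, against 0.473 ± 0.0095 and 0.696 ± 0.037 in these arms at day 4 and 0.41 ± 0.014 at day 2. CD4 thus exceeded CD8A in 4 of the 5 groups of libraries labelled as CD8 T cells, and the share of CD8 T cells in the cultures is not given in the sources used here. B cell markers split 3 and 3 of 9, with MS4A1 at 6.63 ± 0.31 against 8.9 ± 0.4 CPM; their median was -0.13 with an upward test. Monocyte markers split 1 and 1 of 7 (0 and 1 adjusted over the list alone; median 0.37, mean -0.18). Of the dendritic cell markers 1 of 3 was higher (LAMP3, 5.58-fold), and erythrocyte and platelet markers split 2 and 1 of 3. All 5 fibroblast and epithelial markers were higher (adjusted p = 0.053, and 0.049 with RLE scaling), with COL1A1 at 3.76 ± 0.37 against 0.118 ± 0.013 CPM. Ribosomal protein genes split 2 and 10 of 36 (2 and 7 adjusted over the list alone, 4 and 8 with RLE and 6 and 7 with upper quartile scaling), histone genes 1 and 6 of 14 (2 and 6 with either other scaling), with H2BC21 2.24-fold lower, and mitochondrial transcripts 9 and 1 of 15, with MT-RNR2 1.75-fold higher. Mitochondrial transcripts took 7.4% ± 0.21 of counts in chronic and 5.96% ± 0.25 in acute cells. In data simulated for this day with 200 genes changed, 46.3%, 71.6% and 87.9% of those changed 1.5-fold, 2-fold and 4-fold were recovered. These shares do not carry over to the real comparison, where 66.3% of genes were called.

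**Figure D3:**
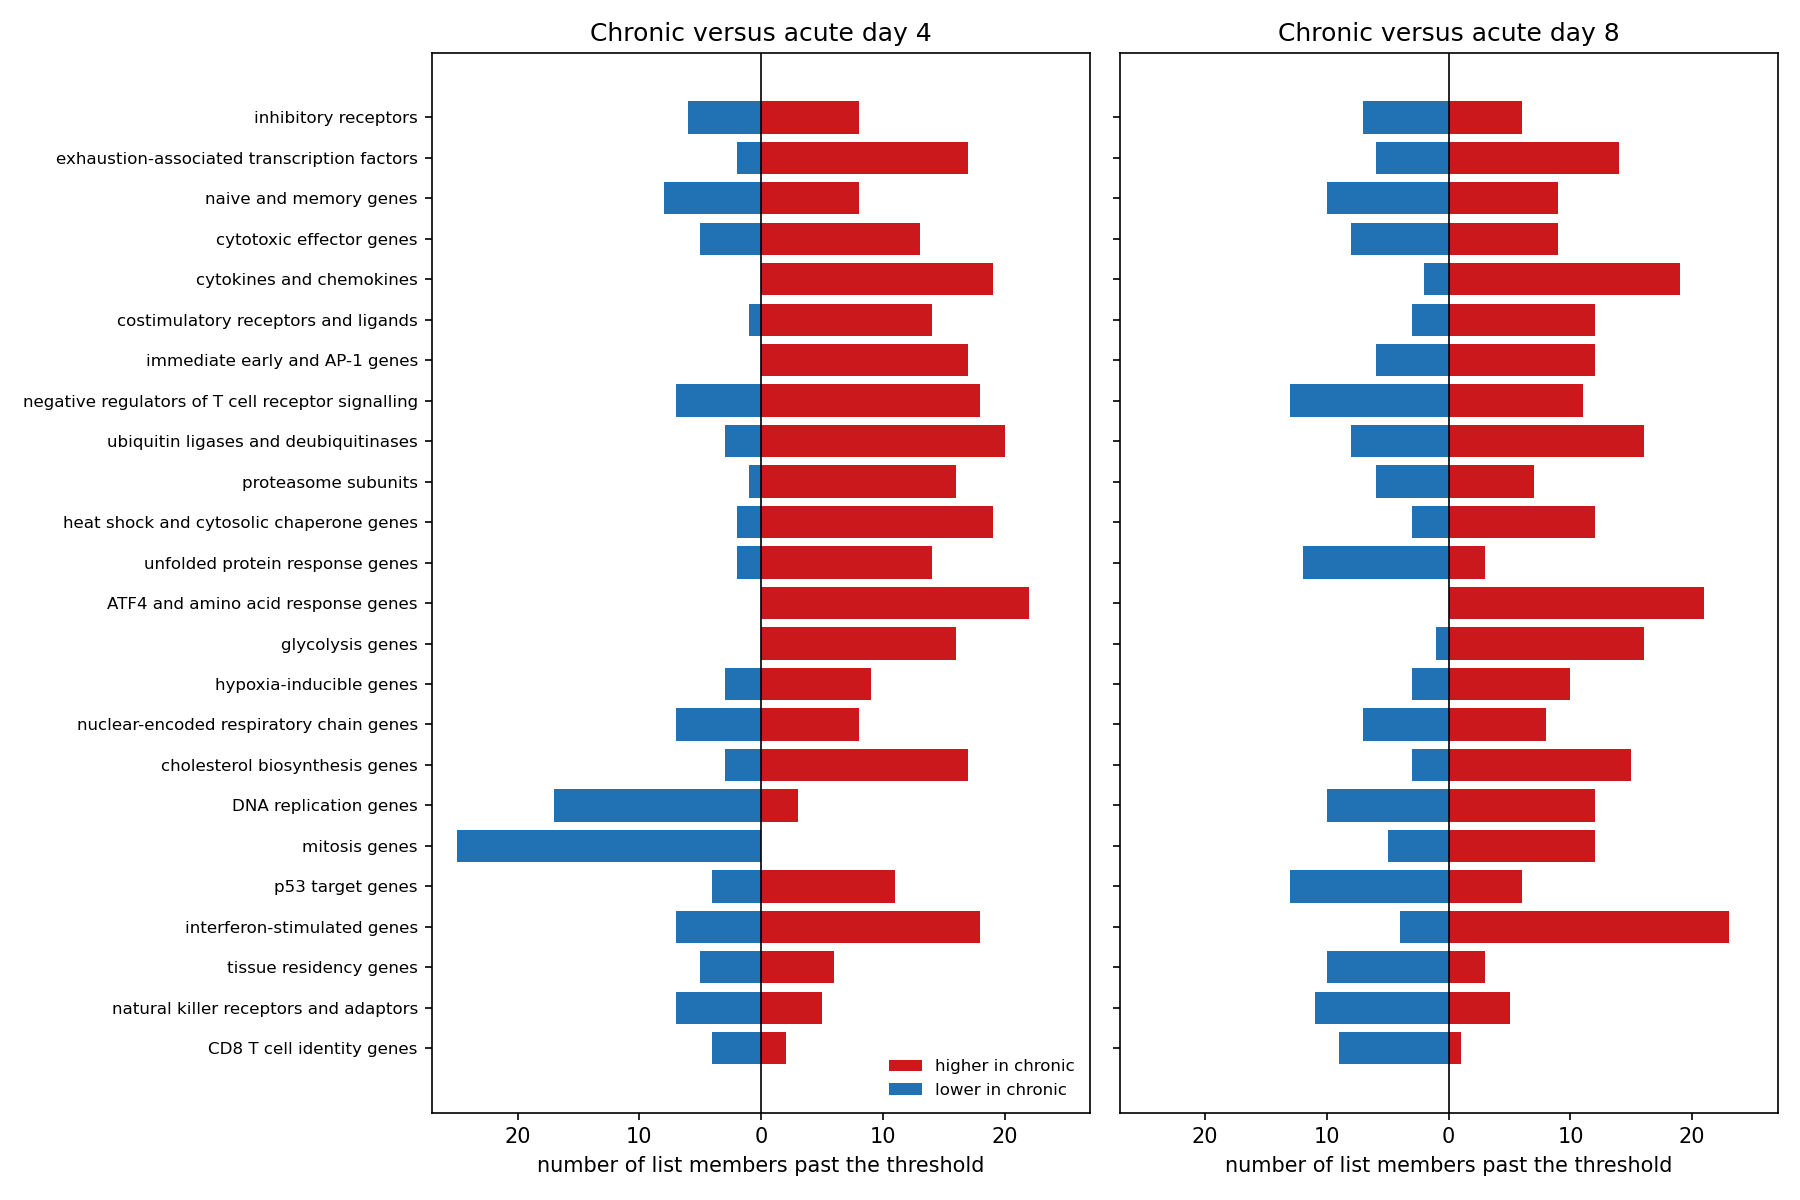
Number of members of 24 gene lists past the threshold in chronic against acute cells at day 4 (left) and day 8 (right), with members higher in chronic cells in red to the right of 0 and members lower in blue to the left. At day 4 all 22 ATF4 and amino acid response genes were higher and all 25 mitosis genes lower; respiratory chain genes at day 4 split 8 to 7, which became 9 against 3 with RLE and 7 against 9 with upper quartile scaling.

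The effects of chronic stimulation at the 2 days were related but not equal. Across genes, which are not independent replicates, the log2 fold changes of days 4 and 8 correlated with r = 0.77 (Spearman 0.66). Genes higher in chronic cells at both days numbered 4400 against 1981 if the lists were independent, and genes lower at both 4574 against 2192, while 1106 were called in opposite directions. Of 10080 genes called at both days, 7190 (71.3%) had the larger absolute change at day 8. A test of the difference itself called 4960 genes with a more positive and 5137 with a more negative chronic effect at day 8. With upper quartile scaling the numbers were 5699 and 4234, and the median of all genes stood at 0.103 in place of 0.02. With the filter of 1 CPM they were 4436 and 4031. Among the most positive differences were those of STC2 (log2 5.29, or 6.35 without acute day-8 replicate 2), the cardiac myosin gene MYH6 (5.28), FMOD (5.14) and SERPINA1 (4.86, a fitted value that rests on 0 counts in acute cells at day 8). Among the most negative were those of PLXNA4 (-4.89), NEFL, PLEK and PLEKHG3 (each near -4.3). The effect on DNA replication and mitosis genes was more positive at day 8 in 19 of 25 and 23 of 25 genes (adjusted p = 1.6e-05 and 8.6e-11; adjusted p = 0.079 for replication with an estimated correlation). That on ATF4 and amino acid response genes was more positive in 17 of 22 (adjusted p = 7.4e-13), although as a set they fell from day 4 to day 8 in both arms. Their median log2 change over these days was -0.43 in chronic and -1.02 in acute cells. The chronic effect was more negative in 15 of 19 cytotoxic effector genes (adjusted p = 3.2e-18), 17 of 22 p53 target genes (adjusted p = 1.4e-11) and 16 of 20 unfolded protein response genes (adjusted p = 4.1e-08). The same held for 13 of 16 natural killer receptors (14 adjusted over the list alone; adjusted p = 4.2e-08) and 7 of 11 CD8 T cell identity genes (adjusted p = 3.1e-07). Beside these, the effect on all 4 gamma delta T cell markers was more negative (median log2 -1.44). Several of these differences came mainly from the acute arm. From day 4 to day 8 the median log2 change of cytotoxic effector genes was 1.16 in acute and -0.02 in chronic cells (0.01 with RLE scaling). It was 0.66 and -0.12 for p53 targets, and 0.42 and -0.06 for CD8 T cell identity genes. For unfolded protein response genes it was 0.28 and -0.26, and for natural killer receptors 0.68 and -0.97.

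Without further stimulation all 21 cytokines and chemokines tested fell from day 2 to day 4 (adjusted p = 5.2e-48). The cytokine genes IL9 (71.7 ± 5.9 to 0.0372 ± 0.019 CPM, log2 -10.92), IL3 (-9.59) and IL17F (-8.35) showed the largest decreases, and KLF2 (1.77 ± 0.12 to 81.7 ± 7.6 CPM, 5.54), CACNA1I (5.25) and GPA33 (5.21) the largest increases. GZMB dropped from 3740 ± 250 to 180 ± 16 CPM and IFNG from 419 ± 44 to 8.06 ± 0.48. In all, 8428 genes were higher and 7431 lower at day 4, a share of 53.1% higher that became 64.2% with upper quartile scaling, under which the median of all genes stood at 0.3 in place of 0.084. Of the other lists, 24 of 25 DNA replication genes (adjusted p = 6.6e-19) and 20 of 22 chaperone genes (adjusted p = 3.9e-32) fell, among them HSP90AB1, from 6100 ± 630 to 595 ± 20 CPM, and MCM10 (4.09-fold). So did 29 of 29 proteasome subunits (adjusted p = 3.5e-23, but adjusted p = 0.079 with an estimated correlation). Interferon-stimulated genes rose in 25 of 28 (adjusted p = 2.8e-06, but adjusted p = 0.3 with an estimated correlation), with IFIT2 7.74-fold higher. Naive and memory genes rose in 13 of 19 and fell in 2 (13 and 3 adjusted over the list alone; adjusted p = 9.5e-05 and adjusted p = 0.086 with an estimated correlation), with KLF2 among those that rose. Beside these, 6 of 9 B cell markers rose and 1 fell (adjusted p = 0.0024, but adjusted p = 0.2 with an estimated correlation), with MS4A1 from 14.7 ± 0.25 to 46.5 ± 0.71 CPM, and all 4 gamma delta T cell markers rose, with TRGC2 from 4.23 ± 0.31 to 17 ± 0.49.

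From day 4 to day 8 acute cells gained cytotoxic and CD8 lineage transcripts. GZMA rose from 113 ± 4 to 596 ± 54 CPM, the cytotoxic granule gene NKG7 from 67.3 ± 6.5 to 353 ± 27, CD8A from 230 ± 2.6 to 688 ± 11 and TOX from 5.13 ± 0.65 to 14.1 ± 0.83. The largest increases were in IL13 (3.57), ZNF683 (3.53) and PHLDA3 (2.94), and the largest decreases in COL6A3 (-3.14), CD22 (-3.02) and the cystine transporter gene SLC7A11 (-3.01). Of 19 cytotoxic effector genes 17 rose and 1 fell (adjusted p = 1.1e-20), and all 11 CD8 T cell identity genes rose (adjusted p = 2.3e-08). With upper quartile scaling 13 cytotoxic genes rose and 2 fell, and 7 of the 11 identity genes rose. All 22 ATF4 and amino acid response genes fell (adjusted p = 1.9e-37), with CHAC1 9.27-fold lower. Naive and memory genes fell in 14 and rose in 2 of 19 (adjusted p = 1.6e-08), with TCF7 from 594 ± 44 to 254 ± 6.2 CPM. Beside these, all 4 gamma delta T cell markers rose and 8 of 9 B cell markers fell (adjusted p = 1.7e-25). All 3 dendritic cell markers and all 3 erythrocyte and platelet markers tested also fell, with median log2 values of -3.41 and -2.24. The median was -0.6 for monocyte markers. Mitochondrial transcripts had a median of -0.19, and their share of counts went from 7.46% to 5.96%. In total 5696 genes rose and 6396 fell, a share of 47.1% higher that became 30.8% with upper quartile scaling, which put the median of all genes at -0.193 in place of -0.054. More genes rose than fell with RLE scaling (6344 and 5742, or 52.5% higher), the DESeq2 test (6130 and 5236) and the filter of 1 CPM (5334 and 4448).

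In cells kept under stimulation, 8017 genes rose and 7152 fell from day 2 to day 4. The share of 52.9% higher became 62.6% with upper quartile scaling, which put the median of all genes at 0.23 in place of 0.062. The largest increases were in the arginine synthesis enzyme gene ASS1 (0.319 ± 0.018 to 36.4 ± 1.9 CPM, log2 6.82), SERPINA1 (5.98) and FMOD (5.82), and the largest decreases in IL9 (-8.81), IL5 (-5.35) and IL10 (-4.16). ATF4 and amino acid response genes rose in 21 of 22 (adjusted p = 2.1e-16). Interferon-stimulated genes rose in 24 and fell in 2 of 28 (adjusted p = 2.4e-15, but adjusted p = 0.078 with an estimated correlation), with IFI44L 12.1-fold higher. Inhibitory receptors rose in 13 and fell in 2 of 16 (adjusted p = 4.7e-06), with LAYN 8.99-fold and LAG3 3.72-fold higher. In acute cells over the same days 10 of them rose and 5 fell. There camera gave adjusted p = 0.06, or 0.04 without acute day-4 replicate 2 and 0.39 with an estimated correlation. The median log2 change was 0.66 in acute and 0.95 in chronic cells. Of the other lists, 24 of 25 DNA replication genes (adjusted p = 1.3e-35) and 17 of 21 cytokines (adjusted p = 1.6e-10) fell. Naive and memory genes rose in 14 and fell in 2 of 19 (median log2 0.88). Their rise over these days was thus not particular to acute cells, where 13 rose and 2 fell (median log2 0.48). As in acute cells over the same days, 19 of 22 chaperone genes fell, while 1 rose, or 2 adjusted over the list alone (adjusted p = 6.1e-27), and all 29 proteasome subunits fell (adjusted p = 1.7e-20, but adjusted p = 0.07 with an estimated correlation). Beside these, 8 of 9 B cell markers rose and 1 fell (adjusted p = 0.013, but adjusted p = 0.27 with an estimated correlation), and of the gamma delta T cell markers 3 rose and 1 fell. From day 4 to day 8, 5124 genes rose and 5915 fell, but 5584 and 5433 with RLE scaling, 5180 and 5052 with the DESeq2 test, 5244 and 3932 with the filter of 1 CPM, and 5906 and 5674 in a fit of only the libraries compared. Upper quartile scaling went the other way, with 4405 and 6725. All 25 DNA replication genes (adjusted p = 4.7e-28) and all 25 mitosis genes (adjusted p = 5.2e-21) rose, such as RRM2 (210 ± 4.5 to 457 ± 6.6 CPM) and CDK1 (135 ± 4 to 270 ± 10). Of 21 cytokines 13 rose while 3 fell (adjusted p = 1.7e-17), with CCL1 from 0.884 ± 0.075 to 46.5 ± 1.6 CPM and CSF2 from 23.6 ± 0.06 to 232 ± 27. MYH6 (4.43) followed CCL1 (5.71) among the increases, and the largest decreases were in LY9 (-4.15), KLF3 (-4.14) and the pseudogene CCR12P (-4.04). Naive and memory genes fell in 17 and rose in 1 of 19 (adjusted p = 1e-12), with CD28 1.83-fold lower, and 8 of 9 B cell markers (adjusted p = 1.1e-16) and 3 of 4 gamma delta T cell markers fell. Median log2 values were -1.68 for monocyte markers, -0.72 for erythrocyte and platelet markers and -0.31 for ribosomal protein genes. CD8A went from 164 ± 1.8 to 121 ± 4 CPM.

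Several genes central to T cell dysfunction could not be compared. PDCD1, which encodes PD-1, had 0 counts in all 15 libraries, and TNF stood at 0.0311 CPM on average over the libraries, CCL3 at 0.00224, CCL4 at 0.043 and ID3 at 0.00074. All of these are annotated both on a chromosome and on an alternate contig of the assembly. Of 1127 protein-coding genes so annotated, 846 (75.1%) lay below 0.1 CPM, against 4726 of 17711 (26.7%) of the others.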

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

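In this part, the tests of a smaller share of CD8 T cells were chosen only after the result was seen. The effect of chronic stimulation differed between days 4 and 8, by edgeR's test of the difference, in 104 of the 125 genes named in the comparisons of the arms, 50 with a more positive and 54 with a more negative log2 effect at day 8. Many of these genes were named for large effects, some for the difference itself; of all 22703 genes tested, 44.5% differed. Values below are the day-8 effect minus the day-4 effect.

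The largest positive differences among these genes, STC2 (5.29), MYH6 (5.28), FMOD (5.14) and SERPINA1 (4.86), were followed by INSM1 (4.04), CXCL13 (3.95), COL6A3 (3.61), IL21 (3.5) and BARX2 (3.43). Without acute day-8 replicate 1 the values of INSM1 and BARX2 were 7.3 and 6.18, without acute day-8 replicate 2 that of STC2 was 6.35, and with limma-voom that of SERPINA1 was 2.87. Further positive differences were ALDH1L2 2.64, CHAC1 2.6, CD200 2.21, MYB 2.16, IFI44L 2.07, CTLA4 1.95, IL3 1.87, VEGFA 1.86, P4HA2 1.73, ZBED2 1.72, PFKFB4 1.65, MX1 1.44, COL1A1 1.43, HSPB1 1.42, IL2 1.35, ENTPD1 1.31 and CD101 1.21. Below 1 lay USP18 0.99, BUB1B 0.92, NDFIP2 0.83, LAMP3 0.8, CENPF 0.78, CD4 0.68, EGR3 0.66, MT-RNR2 0.65, CCR7 0.64, MCM6 0.62, BATF3 0.53, KLHL6 0.5, DUSP4 0.47, GZMB 0.46, TCF7 0.41, SIAH2 0.4, SQLE 0.37, KIF11 0.34, PMAIP1 0.34, IL7R 0.33, MS4A1 0.33, AQP3 0.28, EDEM1 0.28 and LEF1 0.18.

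The largest negative differences among these genes were PLXNA4 -4.89, NEFL, PLEK and PLEKHG3 each -4.3, GZMA -4.03, PTGDR2 -3.96, LAIR1 -3.94, KLF3 -3.84, KLRG1 -3.7, CCR2 -3.58, VSIG1 -3.35, KLRB1 -3.18 and CD244 -3.15. They were followed by FCGR3A -2.9, EOMES -2.84, ZNF683 -2.69, KLF2 -2.62, CD300A -2.46, PHLDA3 -2.46, RAP1GAP2 -2.28, FOS -2.19, CD8A -2.02, ITGA1 -1.84, SESN1 -1.8, PRF1 -1.76, TOX -1.66, TRGC2 -1.56, HSPA5 -1.55, CD8B -1.52, TRDC -1.52, EGR1 -1.5, CACNA1I -1.45, TNFRSF9 -1.39, GADD45A -1.33, H2BC21 -1.26, CRELD2 -1.23 and XCL1 -1.15. Smaller ones were IFNG -0.93, TIGIT -0.91, FOXP3 -0.88, FASLG -0.86, BACH2 -0.78, DNAJB1 -0.63, BIRC3 -0.57, LCK -0.51, KLRC1 -0.5, PSMD13 -0.49, GZMH -0.41, HMGCS1 -0.41, PSMC5 -0.41, BHLHE40 -0.32, HSP90AB1 -0.29, CCNE2 -0.28 and PKM -0.23.

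In fits that left out each of 12 libraries in turn, 7 of the 104 genes lost the call at least once and none changed sign. EDEM1 lost it without acute day-4 replicate 1 (adjusted p = 0.062), COL1A1 without acute day-4 replicate 3 (0.95, adjusted p = 0.052), and PKM without chronic day-4 replicate 1 or chronic day-8 replicate 1 (adjusted p = 0.058 and 0.059). IL2 lost it in 7 of these fits, with the highest adjusted p without acute day-4 replicate 3 (0.47 and adjusted p = 0.64). LEF1, AQP3 and CCNE2 lost it in 7, 6 and 5 fits, with an adjusted p of at most 0.12, 0.068 and 0.064.

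As sets by camera, 16 lists differed between days. The median difference was positive for ATF4 and amino acid response genes (0.69), mitosis genes (0.6), interferon-stimulated genes (0.57) and DNA replication genes (0.44). It was negative for natural killer receptors (-1.23), cytotoxic effectors (-1.06), p53 targets (-1.04), tissue residency genes (-0.83), immediate early genes (-0.76), histones (-0.66), costimulatory molecules (-0.64), unfolded protein response genes (-0.57), CD8 T cell identity genes (-0.53), negative regulators (-0.35), exhaustion-associated transcription factors (-0.21; 7 genes more positive and 8 more negative, 8 and 8 adjusted over the list alone, but 9 and 8 with upper quartile scaling) and proteasome subunits (-0.19). With an estimated correlation 10 of the 16 passed, and the calls lost were those of interferon-stimulated genes (adjusted p = 0.49), DNA replication genes (0.079), immediate early genes (0.14), histones (0.53), exhaustion-associated transcription factors (0.069) and proteasome subunits (0.77). The histone call (adjusted p = 0.046) was lost without acute day-4 replicate 1 (0.054), chronic day-4 replicate 2 (0.058), acute day-8 replicate 1 (0.065) or chronic day-8 replicate 1 (0.053). Ribosomal proteins passed only without acute day-4 replicate 3 (0.014), acute day-8 replicate 2 (0.028) or acute day-8 replicate 3 (0.036), and hypoxia-inducible genes only without acute day-8 replicate 1 (0.048).

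CD8A and CD8B were lower and CD4 higher in chronic than in acute cells at day 8, in libraries labelled as CD8 T cells. A smaller share of CD8 T cells in the chronic than in the acute wells may contribute. From day 4 to day 8 the ratio of CD8A to CD4 CPM went from 0.696 to 2.64 in acute cells. In chronic cells it went from 0.473 to 0.276, so that the larger change lay in the acute arm. Of 8 other genes used more by CD8 than by CD4 T cells the median log2 fold change was -1.39. Of these 5 fell, while KLRC3 (0.76), KLRC4 (0.34) and CRTAM (2.11) rose. KLRC3 (2.34 against 1.38 CPM) and KLRC4 (2.59 against 2.04) were low and share sequence with close copies. CRTAM, also in the costimulatory list, was higher in chronic cells at day 4 too. A change in share and a change in expression thus cannot be told apart for CD8A and CD8B. A smaller share of CD8 T cells alone does not account for 415 genes that fell by more than CD8A itself (95% bounds, lower bound of CD8A -2.62). Among them were GZMA, KLF2, CCR2 and PTGDR2. This holds only if CD8 T cells alone make CD8A and the mix of cells within the CD8 T cells and within the rest stayed alike. A shift between subsets could lower a gene by more than CD8A and was not tested. For the other 2483 of the 2898 genes that fell at least 2-fold, the comparison with CD8A decides nothing. CD4 RNA exceeded CD8A in 4 of the 5 groups, so that the share of CD8 T cells at the start is itself uncertain. The gamma delta markers TRDC and TRGC2 were also lower in chronic cells, at log2 -2.03 and -2.22, where a smaller share of CD8 T cells alone would raise other cells alike. From day 4 to day 8, however, all 4 gamma delta markers rose in acute cells, as CD8A did, and 3 fell in chronic cells. These markers therefore do not separate a change in the make-up of the wells from a change in expression. An effect of the chronic stimulation within each cell stays open and was not tested.

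For the number of genes whose effect differed between days (10097), 9 of the 100 splits drawn from 200, the real one included, gave as many. Of the other 8, the highest (15577) swapped the arms of 1 day, which turns the difference into a sum, and 7 (10193 to 10631) kept the real grouping of the arms at 1 day. These hold a real difference between the arms, so that their number does not bear on chance. The 82 drawn splits that kept the grouping of neither day gave 0 genes with edgeR. Their groups mix wells of both arms, so the difference between the arms enters the spread within groups, and this 0 is no measure of false calls. For the other comparisons, 3 libraries against 3 make only 10 splits, too few for a share under 0.05. In each, only 1 split, the real one, gave as many genes. The other splits mix the 2 groups in the same way, so that a 0 there is no measure of false calls either. The real values and the highest other were 12592 and 0 for chronic against acute at day 4, 15044 and 0 at day 8, 15859 and 0 for acute day 4 against day 2, 12092 and 0 for acute day 8 against day 4, 15169 and 0 for chronic day 4 against day 2, and 11039 and 0 for chronic day 8 against day 4.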

How the results depend on the processing

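Only leaving out the genes on alternate contigs was chosen after seeing the data; it gave 5941 higher and 6474 lower genes at day 4 and 7375 and 7450 at day 8. Of 8528 values of named genes under the alternatives, 8487 kept their direction and side of the threshold, 28 lost and 10 gained a call, and 3 reversed: ITGA2B at day 4 gave 0 with DESeq2 and, without 1 library, -0.11 to 0.1, the highest without acute day-4 replicate 3. PRF1 at day 8 gave -0.02 to 0.13, the lowest without chronic day-8 replicate 2; neither was past the threshold, and the cause was not tested. Lists called numbered 18, 13, 16, 16, 20, 19 and 14 for day 4, day 8, their difference, acute day 4 against day 2, acute day 8 against day 4, and the same steps in chronic cells. With an estimated correlation they numbered 9, 4, 10, 6, 12, 8 and 7, and with fry 25 at day 8, 29 and 29 for the steps from day 2 and 28 for chronic day 8 against day 4, since fry compares with no other genes. In the order above, the counts without 1 library were 5608 to 5893 higher and 5918 to 6099 lower, 7130 to 7438 and 7175 to 7392, 4600 to 4924 and 4747 to 5096, 7961 to 8815 and 6850 to 7260, 5194 to 5461 and 5758 to 6020, 7534 to 8423 and 6429 to 6918, and 4531 to 4873 and 5301 to 5503. Which direction held more calls turned with RLE scaling at day 4 (6416 higher and 6031 lower), day 8 (7675 and 7300), acute day 8 against day 4 (6344 and 5742) and chronic day 8 against day 4 (5584 and 5433), and with the DESeq2 test in the same 4 comparisons (6190 and 5526, 7646 and 7101, 6130 and 5236, 5180 and 5052). It turned with upper quartile scaling at day 8 (7817 and 7156) and in the difference between days (5699 and 4234), and with no filter at day 8 (8322 and 7663). The filter of 1 CPM turned it in the difference between days (4436 and 4031), acute day 8 against day 4 (5334 and 4448) and chronic day 8 against day 4 (5244 and 3932), and a fit of only the libraries compared in the last of these (5906 and 5674). At day 8 it also turned without acute day-8 replicate 1 (7438 and 7233), chronic day-8 replicate 1 (7215 and 7201) or chronic day-8 replicate 2 (7250 and 7245). Upper quartile scaling gave 3693 genes higher in acute day 8 than day 4, against 5696. The filter of 1 CPM in 3 libraries, which tests fewer genes, gave 3932 genes lower in chronic day 8 than day 4, against 5915, and moved the 2-fold counts most: to 1372 and 956 at day 4 (main 2321 and 1865), 2147 and 1671 at day 8 (3877 and 2898), 1349 and 892 for their difference (2305 and 1471), 2463 and 1886 (4357 and 2929), 415 and 1135 (649 and 2630), 2300 and 1484 (4087 and 2315), and 652 and 874 (1132 and 1952) for the steps in time. The correlation of the day-4 and day-8 effects was 0.77 with DESeq2 and with the replicate block, and 0.84 for genes of at least 10 CPM. The replicate numbers did not pair the wells (correlation of deviations -0.13 to 0.08 over 18 pairs, 0 of them over 0.1); with the replicate block no count moved by over 1.5 times, and LEF1 at day 8 was the only named call lost (adjusted p = 0.075). Depth limits genes with few counts in 1 arm, such as BARX2, whose day-8 value was 13.26 without acute day-8 replicate 1.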

Other observations

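Families of genes that share a symbol prefix were not among the fixed lists and were tested, all 83 with at least 15 genes, only after the data were seen. By camera, genes with the nuclear receptor prefix NR were higher as a set in chronic cells at day 4, with 10 higher and 4 lower of 17 (adjusted p = 1.9e-07; adjusted p = 0.0062 with an estimated correlation), and at day 8, with 9 and 4 (adjusted p = 0.0044; adjusted p = 0.17 with an estimated correlation). NR4A1 and NR4A3, members of this family, were also in the fixed list of exhaustion-associated factors. Of 63 interleukin and interleukin receptor genes (prefix IL), 37 were higher and 17 lower at day 4 (adjusted p = 0.00022; adjusted p = 0.012 with an estimated correlation), and 33 and 23 at day 8 (adjusted p = 0.52). Of 17 TNF receptor superfamily genes 10 were higher and 6 lower at day 4 (adjusted p = 0.00016; adjusted p = 0.18 with an estimated correlation), and 8 and 7 at day 8 (median log2 -0.31, adjusted p = 0.93, direction of the test upward). Collagen genes were higher in 12 and lower in 6 of 24 at day 4 (adjusted p = 0.069) and in 13 and 5 at day 8, with a median log2 fold change of 1.61 (adjusted p = 0.027; adjusted p = 1 with an estimated correlation).

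PDCD1, CCL3 and CCL4 had counts of 0 or near it in all groups, although activated T cells are known to express them. Reads lost because the sequence is duplicated on an alternate contig may account for this. A test set beforehand took at least 5 of 10 genes with a mean below 1 CPM as speaking for it, and at most 1 as speaking against it. The limit of 5 was just met. Of 10 genes of the major histocompatibility region that nearly every cell uses, and that are annotated in this way, 5 lay below 1 CPM, among them RPS18 at 0.219 and GNL1 at 0.0122, while TUBB stood at 37 and PSMB8 at 17.1. The level of such genes differs from gene to gene, so that each is uncertain, and the low counts are no measure of the cells' expression.

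A hypothesis set before its test was that the day-8 difference between the arms resembles the state at day 2 of activation. Across genes, which are not independent replicates, the log2 differences of chronic against acute at day 8 and of day 2 against acute day 4, which share no library, correlated with r = 0.296 (Spearman 0.21), just under the 0.3 set beforehand for a resemblance and above the 0.1 set against it. The highest absolute value in 100 random pairings of genes was 0.015. Such pairings break the relation between genes, so that this value is no baseline for 2 comparisons within the same cells. Among genes with a mean of at least 10 CPM r was 0.38, and 6921 of 11345 genes called in both (61%) had the same direction. The test leaves open whether sustained stimulation may hold cells partly in their day-2 state.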
